A study of Chlorella sorokiniana and Chromochloris zofingiensis with 12 samples.

How the data were processed

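Small RNA was measured by sequencing in 12 libraries made from total RNA of the green algae Chlorella sorokiniana and Chlorella zofingiensis, each in a normal and a stress culture, with 3 libraries per group. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the NEBNext Multiplex Small RNA kit, and groups and replicate numbers were taken from the labels. The aligner, the trimming settings and their versions are not given in the sources used here. The submitters' processing notes name DESeq, without a version, and the Arabidopsis thaliana build TAIR9.

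The authors deposited 2 kinds of table, which were analysed apart. The tag table, named after the CLC software, holds whole-number counts of reads per small RNA sequence, per the file headers, for each library of a species. Each library has exactly 100 tags above 0, so a count of 0 there means that a tag was outside that library's 100 commonest tags. The sum of a library's listed counts is therefore not its sequencing depth, and the full depth was not analysed here. The tag table also holds a normalized signal made by the authors, per the file headers. In 3 of the 12 libraries that signal equals the counts, and the other 9 share a total of 237584, so it was not used for tests. The annotation sheets, named after the omiRas tool, hold deposited counts of reads per Arabidopsis miRNA, tRNA, rRNA or snoRNA entry, per the file headers. A read was counted at every entry to which it maps, so entries with similar sequence share reads. A second column of these sheets gives a signal that the authors made by dividing the counts by the number of mapping loci, per the file headers. The authors' deposited comparison tables hold p-values and FDR values of their own tests, per the file headers, with other values such as signed fold changes, normalized group means and predicted folding energies.

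Counts were compared between stress and normal with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM normalization, the filterByExpr filter, robust dispersion fitting and Benjamini-Hochberg adjustment, and an adjusted p below 0.05 was called. Each species was fitted alone with condition as the only term, on 6 libraries. An RNA missing from a library's annotation sheet was taken as 0. The design had planned miRNA families from the tag table, but its tags carry no miRNA names, so families were summed from the miRNA precursor entries of the annotation sheets, with the letter and arm of each name removed. The difference between the species was tested as an interaction over all 12 libraries on entries named in both species. Shares of RNA classes were compared with an exact two-sided permutation test (scipy 1.17.1), where 3 libraries against 3 cannot give a p below 0.1. Lists of miRNAs with at least 3 tested members were tested with fry (limma 3.58.1). Precursors were folded again with RNAfold 2.7.2. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

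The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The rule named, per species and table, the 10 called features with the largest change in each direction whose stress values all lay above or all below the normal values, the 10 features with the highest mean, up to 4 members of each of 8 lists and the 5 smallest p-values in each direction of the authors' tables, with identical values named once. Sums over overlapping tags were chosen after the tags had been seen: tags sharing 12 bases, the last base removed, were joined into a group and their counts summed. Tag groups and other features named outside the rule were chosen after their values were seen. Tags that resemble sequence of another organism are not printed, although the rule named some of them.

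Where a tag was unlisted in every library of a group, a lower bound of the fold change was computed against the mean of that group's smallest listed shares. For annotation entries and families with 0 reads in every library of a group, the bound was computed against 3 counts per library. Fitted fold changes of such features depend on the prior count and are no bounds. Both kinds of bound are ratios of shares of listed or annotated counts, with no composition factor. With TMM and unlisted tags at the smallest listed count, called tags listed in stress alone rose by less than their bounds in both species. For such tags the bounds therefore hold for shares of listed reads only. Intervals and floors cover counting error only, since the libraries carry no molecular identifiers.

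Listed reads per library ranged from 46518 to 406492 in C. sorokiniana and from 81672 to 500007 in C. zofingiensis. Annotated counts, summed over entries, ranged from 2718 to 26102 and from 14601 to 280404, with a read counted at every entry it maps to. In chi-square tests of the counts, replicate pairs differed by 2.39 to 378 per degree of freedom over 24 pairs. Each library was counted as its own sample. The chi-square tests cannot justify this, since they compare the pairs with counting error alone. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicate numbers were taken to pair libraries where every same-numbered correlation of deviations from the group means was above 0.1. The C. sorokiniana libraries met this rule, at 0.132 to 0.541 in the tag table and 0.173 to 0.241 in the annotation sheets. In that tag table, though, normal replicate 2 correlated better with stress replicate 3, at 0.29. The C. zofingiensis libraries did not meet it, but their annotation sheets reached 0.646 and 0.695 for replicates 1 and 2, against 0.0125 for replicate 3. Correlations covered tags above 0 in all libraries, or distinct entries past the filter. No label says what the number stands for.

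The test was checked on simulated counts drawn with the real means and library sizes, with changed features making up 1 in 3. With tagwise dispersions and a 4-fold change, the test recovered 48.6% of the changed tags in C. sorokiniana and 78.9% in C. zofingiensis, and 64.5% and 94.6% at 16-fold. For annotation entries it recovered 95.9% and 56.8% at 4-fold and 100% and 90.3% at 16-fold, and for the species difference 19.0% and 84.8%. For the families it recovered 2 of 3 at 4-fold and 3 of 3 at 16-fold in each species. The number of unchanged features called lay between 0 and 5. A version with the common dispersion had been run before tagwise dispersions were chosen. With it, a 4-fold change was recovered for 0% of changed tags in C. sorokiniana, 44.7% in C. zofingiensis, and for 100% and 19.2% of annotation entries and 13.2% of the species difference.

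Alternatives were DESeq2's size factors in edgeR, library totals with no composition factor, no filter, a filter of 10 counts in 3 libraries, the Wald test of DESeq2 1.42.0, the replicate number as a block, an adjusted p below 0.01, identical counts entered once, and each library left out in turn. Added after seeing the data were unlisted tags set to the smallest listed count, tags listed in all 6 libraries, tags summed by overlap or by their first 15 bases, counts per mapping locus with limma, entries whose commonest tag has at least 16 bases, families with whole-sheet totals or by their largest member, and the species difference on tags or families. No pseudocount was varied as an alternative, but counts per locus took an offset of 0.1, and edgeR's fitted fold changes use a prior count. Deposited copies of other tables were not used here, and columns of per-sample values without a matching sample numbered 0.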

Results

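Small RNA profiles were compared between normal and stress cultures of 2 green algae, Chlorella sorokiniana NIES-2168 and Chlorella zofingiensis ATCC30412. Normal cultures grew in Bold's Basal Medium at 27 °C under continuous light of 10 µmol photons, with shaking at 30 rpm. Stress was applied in mid log phase by raising the light to 100 µmol photons and adding 2% glucose. Each of the 4 groups had 3 libraries. The 100 commonest tags of a library held 46518 to 406492 reads in C. sorokiniana and 81672 to 500007 in C. zofingiensis. Counts matched to Arabidopsis RNAs, summed over entries that can share reads, came to 2718 to 26102 and to 14601 to 280404 per library. Tags were not matched to an algal genome, so they are identified by their sequence. Their RNAs of origin were not identified, apart from the matches to rRNA given below. For rRNA, only a few universal primers and a motif of bacterial 5S rRNA were searched for. Primers for other parts of 18S, 5.8S and 28S rRNA matched no listed tag, but a tag without a match can still be rRNA. Fragments of rRNA were therefore not told apart from other small RNAs.

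The question for C. sorokiniana was which small RNAs changed under strong light with glucose. Tags that overlap each other fell into 41 groups, of which 11 of 22 tested passed, 7 higher and 4 lower. With the replicate block 7 passed, all higher, 6 of them among the 11, and none of the 4 lower groups did. The group led by GCGGAAGGATCATTGA rose by 3.29 ± 0.18 (SE) on the log2 scale, from 1572, 463 and 202 reads in normal libraries to 5622, 5175 and 4164 under stress (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000137). Unlisted tags count as 0 in such sums, and as a single tag the lead tag rose by 2.11 ± 0.15 (edgeR, Benjamini-Hochberg adjusted p = 0.00175). The tag CCTTGTATTCTTGCTTGA, a group of its own, rose by 3.87 ± 0.62, from 451, 440 and 239 reads to 5365, 5641 and 6385 (edgeR, Benjamini-Hochberg adjusted p = 0.00581). In the fit of single tags, scaled apart from that of the groups, it rose by 3.40 ± 0.65 (edgeR, Benjamini-Hochberg adjusted p = 0.0116). The groups led by TCAGCCGTTGTTCTTACGATTTGTA and GACCGAATGATTTTGACA rose by 1.58 ± 0.37 and 1.09 ± 0.25 (edgeR, Benjamini-Hochberg adjusted p = 0.0168 for each). As single tags their lead tags did not pass, at 0.18 ± 0.35 and 0.48 ± 0.26 (edgeR, Benjamini-Hochberg adjusted p = 0.763 and 0.235). The largest group, 21 tags led by TGTCTGCCTCAGCGTCGGTA with 33.0% of the listed reads, had a log2 fold change of -0.11 ± 0.03 (edgeR, Benjamini-Hochberg adjusted p = 0.0182, and 0.0672 with the replicate block), and -0.30 with library totals alone (adjusted p = 0.0126). Tags led by ACCTGGTTGATCCTGCCA, 4 in all, each sharing at least 12 bases with a universal primer for the start of 18S rRNA, were at -0.03 ± 0.19 (edgeR, Benjamini-Hochberg adjusted p = 0.906), and at -0.23 with library totals alone (0.391).

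Among single tags of C. sorokiniana, members of these groups moved apart. The most abundant tag, TGTCTGCCTCAGCGTCGGTA, fell by 0.98 ± 0.10, and GTCTGCCTCAGCGTCGGTA fell by 0.76 ± 0.07 (edgeR, Benjamini-Hochberg adjusted p = 0.00175 for each). The longer GGGCATGTCTGCCTCAGCGTCGGTA was listed in the stress libraries alone, with 862, 1138 and 767 reads, and was at least 5.52-fold higher. Also listed in stress alone were AACAGACCGAATGATTTTGACA, at least 5.74-fold higher, and CTGCGGAAGGATCATTGA, at least 5.11-fold higher. AAGACAACTCTCAACA and AAGACAACTCTCAACAA fell by 1.78 ± 0.19 and 1.91 ± 0.23 (edgeR, Benjamini-Hochberg adjusted p = 0.00175 for each). With another A at the start, AAAGACAACTCTCAACA and AAAGACAACTCTCAACAA were listed in stress alone and were at least 2.88-fold and 3.79-fold higher, with adjusted p of 0.00175 each that became 0.313 and 0.175 with the replicate block (edgeR, Benjamini-Hochberg). AAGACAACTCTCAACAACGGATAA was listed in the normal libraries alone and was at least 2.46-fold lower. The abundant TCGACCTGAGCTCAGGCAA was at -0.85 ± 0.22, AACTCTCAACAACGGATAA at -0.70 ± 0.17 and AAGCTGTGGGATATTA at -1.01 ± 0.26 (edgeR, Benjamini-Hochberg adjusted p = 0.0325, 0.0277 and 0.0315). All 3 calls ended with library totals alone (adjusted p = 0.0644, 0.054 and 0.0678, edgeR, Benjamini-Hochberg), and AAGCTGTGGGATATTA also with the replicate block (0.0515). Each was also lost in part of the leave-outs, TCGACCTGAGCTCAGGCAA without any normal replicate or stress replicate 2 or 3 (0.0596 to 0.154), AACTCTCAACAACGGATAA without normal replicate 1 or 3 or stress replicate 2 or 3 (0.0609 to 0.0987) and AAGCTGTGGGATATTA without any library but normal replicate 3 (0.0904 to 0.142). The 10 commonest tags took 61.4% ± 0.83 (SD, n = 3) of listed reads in normal and 46.3% ± 1.41 in stress libraries (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows).

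In all, 42 of 106 tags tested in C. sorokiniana passed an adjusted p of 0.05, with 24 higher and 18 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg). The values of the groups did not overlap for 66 tags or 62.3%, where chance gives 10%. With the replicate block 20 tags passed, 9 higher and 11 lower, and among tags listed in all 6 libraries 21 passed. Library totals without a composition factor gave 28 higher and 13 lower, with the median log2 fold change of the tested tags at 0.32 in place of 0.07. Of the 21 called tags unlisted in a whole group, 3 that were listed in normal libraries lay below the level at which a fold could be bounded, among them AATACCTCTGCAACATCCA and TTAAGTTGCTGCAGTA, which did not pass with the replicate block (edgeR, Benjamini-Hochberg adjusted p = 0.496 for each).

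The same question was asked in C. zofingiensis. The group led by TAAAGACCAATTGACA fell by 3.07 ± 0.12, from 11141, 16682 and 15118 reads in normal libraries to 2582, 421 and 386 under stress (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.51e-06). Unlisted tags count as 0 in such sums, and as a single tag the lead tag fell by 2.45 ± 0.22 (edgeR, Benjamini-Hochberg adjusted p = 0.000128). Tags of the group of CGCCTACCGTCGTGCTTCGGCA, with 11.6% of listed reads, fell by 1.66 ± 0.31, and those of CGTTCGTAGTCTAGGGA fell by 1.63 ± 0.24 (edgeR, Benjamini-Hochberg adjusted p = 0.00169 and 0.000508). As in the other species, GCGGAAGGATCATTGA led a group that rose, by 2.70 ± 0.21, from 765, 1307 and 1385 reads to 9443, 1820 and 1963 (edgeR, Benjamini-Hochberg adjusted p = 1.86e-05). Tags led by TCAGCCCGTGTTCGGAAGATTTGTA rose by 1.61 ± 0.19 as a sum, from 12723, 17051 and 19368 reads to 63098, 12610 and 13036 with 500007, 81672 and 82565 listed reads in those 3 stress libraries (edgeR, Benjamini-Hochberg adjusted p = 0.000145). The lead tag itself went the other way in the fit of single tags, at -0.66 ± 0.17 (edgeR, Benjamini-Hochberg adjusted p = 0.0193). The group led by TGTCTGCCTCAGCGTCGGTA, with 50.4% of listed reads, was at -0.15 ± 0.15 (edgeR, Benjamini-Hochberg adjusted p = 0.367).

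Among single tags of C. zofingiensis, CGCCTACCGTCGTGCTTCGGA fell by 2.96 ± 0.18, from 8127, 15706 and 17363 reads to 2633, 589 and 506 (edgeR, Benjamini-Hochberg adjusted p = 3.95e-05). CGCCTACCGTCGTGCTTCGGCATTA, CGCCTACCGTCGTGCTTCGA and TAAAGACCAATTGACTA were listed in the normal libraries alone and were at least 4.45-fold, 4.21-fold and 3.73-fold lower. CGCCTACCGTCGTGCTTCGGCA, the most abundant member of its group, had a log2 fold change of -0.61 ± 0.22 and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0598). TGCGGAAGGATCATTGA and TTCAGCCCGTGTTCGGAAGATTTGTA were listed in stress alone, with 3456, 643 and 695 reads and with 2374, 656 and 698 reads, and were at least 5.28-fold and 4.83-fold higher. GTCTGCCTCAGCGTCGGTAA, also listed in stress alone, was at least 3.83-fold higher, and these bounds, too, are of shares of listed reads. TGCCTCAGCGTCGGTA, among the 10 most abundant tags, rose by 0.63 ± 0.18 (edgeR, Benjamini-Hochberg adjusted p = 0.0279), and without normal replicate 1 or 2 or stress replicate 1 or 3 its adjusted p was 0.131, 0.142, 0.0718 or 0.0669. A motif of the end of bacterial 5S rRNA, chosen after tags listed in stress alone had been seen, was held by 6 other tags, among them 5 of the 24 called tags listed in stress alone, and no other bacterial RNA was searched for. These 6 tags took 0% of listed reads in each normal library and 1.90% ± 0.18 (SD, n = 3) in stress libraries, a difference that this choice of the motif favours. Reads of 20 to 24 bases made up 55.0% ± 1.54 (SD, n = 3) of listed reads in normal and 47.1% ± 0.81 in stress libraries of C. zofingiensis, and 37.4% ± 0.83 and 32.9% ± 0.57 in C. sorokiniana (exact permutation tests, two-sided, p = 0.1 for each, the smallest possible).

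Of 115 tags tested in C. zofingiensis, 65 passed, 34 higher and 31 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). With the replicate block 21 passed, 9 higher and 12 lower. The values of the groups did not overlap for 78 tags or 67.8%, where chance gives 10%. Unlisted in a whole group were 46 of the called tags, and for 7 of the lower ones no fold could be bounded. Library totals without a composition factor moved the median log2 fold change of the tested tags from 0.05 to 0.44. Among tags listed in all 6 libraries 27 passed, 9 higher and 18 lower. With tags summed by overlap 22 of 31 groups passed, 15 higher and 7 lower. Most of the 15 higher groups had no listed reads in any normal library. Some of the 7 lower groups had none in any stress library. For the groups listed in stress alone, bacterial RNA was not told apart from algal RNA, so the split is not a count of algal responses.

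**Figure D1:**
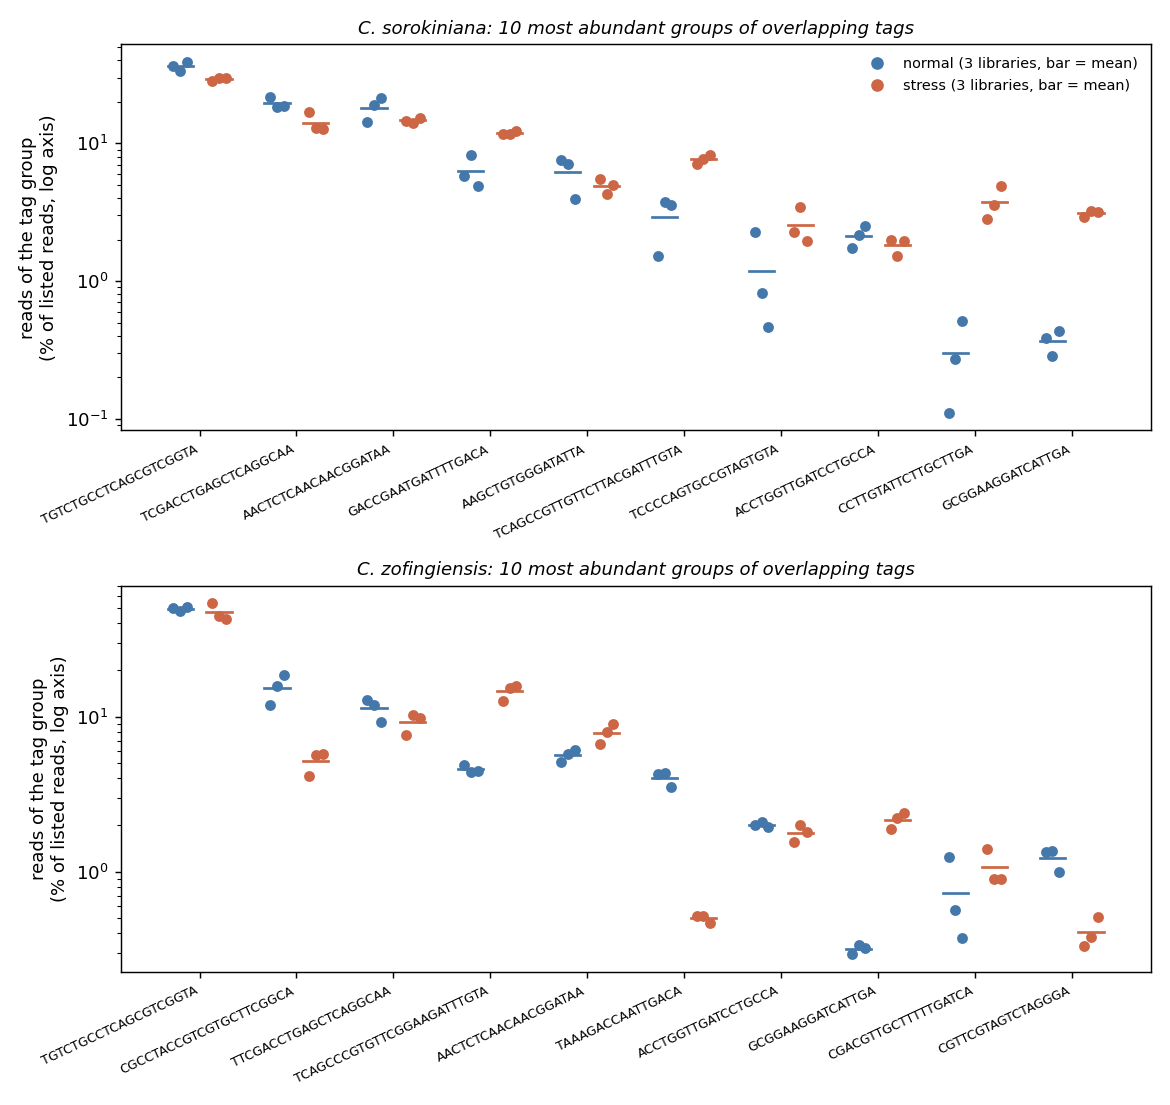
Share of listed reads (percent, log axis) taken by the 10 most abundant groups of overlapping tags in each species, with 1 point per library, 3 normal and 3 stress libraries per group and a bar at the mean. In C. sorokiniana the stress points of the group led by GCGGAAGGATCATTGA lie above its normal points, and in C. zofingiensis those of the group led by TAAAGACCAATTGACA lie below, with log2 fold changes of 3.29 and -3.07.

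Both species shared 39 tags exactly, and tags sharing at least 12 bases with the other species took 71.4% of listed reads in C. sorokiniana and 71.2% in C. zofingiensis. The responses of 7 of 38 shared tags differed between the species (edgeR's interaction test, Benjamini-Hochberg adjusted p below 0.05). GCGGAAGGATCATTGA rose less in C. zofingiensis, by -1.11 ± 0.30 on the log2 scale relative to C. sorokiniana (edgeR, Benjamini-Hochberg adjusted p = 0.0437). AACTCTCAACAACGGATAA differed by 0.76 ± 0.23 in the other direction (edgeR, Benjamini-Hochberg adjusted p = 0.0437). A further shared tag, TCGACCTGAGCTCAGGCA, differed by -0.91 ± 0.27 (edgeR, Benjamini-Hochberg adjusted p = 0.0437).

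Shares of classes are of counts summed over entries, not of reads, since a read counts at every entry it maps to. The tRNA of chromosome 1, 20412928 to 20413000, for example, had 1350 reads in stress replicate 1 of C. sorokiniana, and 8 other entries had the same counts. Among counts matched to Arabidopsis RNAs, tRNA entries took most in both species. In C. sorokiniana they took 82.6% ± 3.60 (SD, n = 3) in normal and 87.3% ± 1.63 in stress libraries (exact permutation test, two-sided, p = 0.2). Entries for miRNAs took 10.5% ± 3.32 in normal and 6.70% ± 0.85 in stress libraries, lower in all 3 stress libraries than in any normal library (exact permutation test, n = 3, p = 0.1, adjusted p = 0.533 over 8 comparisons). Without normal replicate 3 the difference was -2.02 percentage points in place of -3.85, and as a share of entries detected it was 0.06. In C. zofingiensis tRNA took 88.4% ± 9.57 and 90.2% ± 2.08, snoRNA 9.37% ± 7.70 and 8.37% ± 1.30, and miRNA 2.00% ± 1.64 and 1.20% ± 0.92 (exact permutation tests, n = 3, p = 0.9, 1 and 0.5). No class passed, and 3 libraries against 3 could not have given a p below 0.1. Without normal replicate 1 the difference of the miRNA share in C. zofingiensis was 0.07 percentage points in place of -0.81.

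**Figure D2:**
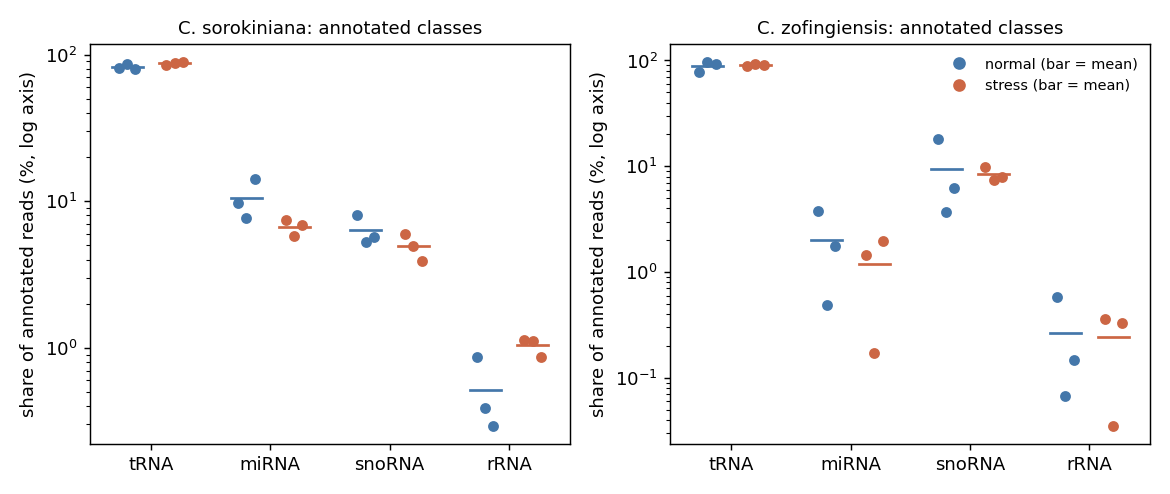
Share of annotated counts, summed over entries that can share reads (percent, log axis), in 4 classes of Arabidopsis RNA entries, with 1 point per library, 3 libraries per group and a bar at the mean. The miRNA share of the stress libraries of C. sorokiniana, with a mean of 6.70%, lies below that of its normal libraries, with a mean of 10.5%, and the other classes overlap or spread widely.

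Among annotated entries of C. sorokiniana the smallest adjusted p was that of a 5S rRNA copy, a part of the large ribosomal subunit, at chromosome 5, 12024975 to 12025093 of TAIR9. It had 0 reads in each normal library and 23, 40 and 25 under stress, at least 2.62-fold higher, or 7.05-fold without normal replicate 3, and kept its call with each library left out in turn (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.54e-07). The precursor ath-mir-5645e rose by 2.88 ± 0.66, from 7, 10 and 0 reads to 98, 108 and 63 (edgeR, Benjamini-Hochberg adjusted p = 9.72e-05, and 0.109 without stress replicate 3). A tRNA entry at chromosome 1, 26382154 to 26382225, rose by 2.27 ± 0.66, from 5, 14 and 0 reads to 81, 73 and 45 (edgeR, Benjamini-Hochberg adjusted p = 0.0027, and 0.0727, 0.101 and 0.174 without normal replicate 1, stress replicate 1 or stress replicate 3). The small nucleolar RNA snoZ267, at chromosome 1, 6466300 to 6466375, rose by 2.51 ± 0.66 (edgeR, Benjamini-Hochberg adjusted p = 0.000939, and 0.0515 and 0.166 without stress replicate 2 or 3). Further entries with 0 reads in each normal library were snoR24, at least 1.30-fold higher, and tRNA entries at chromosome 2, 9137356 to 9137427, and chromosome 5, 7981398 to 7981469, at least 1.52-fold and 1.28-fold higher. Without normal replicate 3 these 3 bounds were 3.51, 4.09 and 3.45, and without normal replicate 1 they were 0.969, 1.13 and 0.954, so 2 of them no longer bounded a rise.

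Other entries of C. sorokiniana were called lower, but these calls depended on the scaling. The precursors ath-mir-396a and ath-mir-396b, named for a miRNA that targets growth-regulating transcription factors in land plants, were at -2.24 ± 0.59 and -2.19 ± 0.59 (edgeR, Benjamini-Hochberg adjusted p = 0.000917 and 0.00115). They did not pass with identical counts entered once (edgeR, Benjamini-Hochberg adjusted p = 0.0505 and 0.0682), nor without normal replicate 1 or 2 or any stress replicate (0.0576 to 0.616). The mature ath-miR-169m, with 389, 353 and 130 reads in normal and 357, 335 and 353 in stress libraries, was at -1.31 ± 0.36 (edgeR, Benjamini-Hochberg adjusted p = 0.00158), turned to 0.11 with identical counts entered once, and did not pass with DESeq2's size factors (0.24) or without normal replicate 2 or any stress replicate (0.195 to 0.643). The 15 tRNA entries sharing the counts of chromosome 1, 2025356 to 2025428, were at -2.01 ± 0.38 (edgeR, Benjamini-Hochberg adjusted p = 2.22e-06), and at -0.75 with identical counts entered once (adjusted p = 0.156) or -1.69 without stress replicate 3 (0.174). The snoRNAs snoR114 and snoR1 were at -2.56 ± 0.57 and -2.29 ± 0.51 (edgeR, Benjamini-Hochberg adjusted p = 6.47e-05 and 6.87e-05), and did not pass without stress replicate 1 (adjusted p = 0.0698 and 0.0828), 2 (0.0776 and 0.17) or 3 (0.469 and 0.499).

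Of the entries tested in C. sorokiniana, 121 tRNA, 27 snoRNA, 6 rRNA, 8 miRNA precursors and 4 mature miRNAs, 55 passed, 18 higher and 37 lower, or 13 and 17 when entries with identical counts were named once (edgeR's quasi-likelihood test, Benjamini-Hochberg). By class, 13 tRNA entries were higher and 21 lower, 3 snoRNA entries higher and 7 lower, 1 rRNA entry higher, 1 miRNA precursor higher and 6 lower, and 3 mature miRNAs lower. With identical counts named once the tRNA entries turned to 8 higher and 3 lower of 32, and snoRNA stayed at 3 and 7 of 18. The split turned with identical counts entered once, to 40 higher and 1 lower, where the median log2 fold change was 1.41 in place of 0.18, and it was 17 and 19 with DESeq2's size factors (median 0.68) and 29 and 30 with library totals alone (median 0.50). Each left-out library turned the split to more higher than lower entries, with 88 and 29, 118 and 20, and 95 and 37 without normal replicates 1, 2 and 3, and 63 and 15, 41 and 16, and 7 and 1 without stress replicates 1, 2 and 3. It was 92 and 33 without a filter, and 3 entries passed among those whose commonest tag has at least 16 bases.

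The lists of miRNAs fixed before held few measured members in C. sorokiniana. Of the nutrient limitation list, miRNAs of phosphate, sulfate and nitrogen supply in land plants, 4 entries were tested and all 4 were lower, also when adjusted over the list alone (limma's fry test for a common direction, Benjamini-Hochberg adjusted p = 0.103). These were ath-miR-169m, ath-mir-169m, ath-mir-399b, at -1.77 ± 0.49, and ath-miR-399b with the same counts, and with DESeq2's size factors none of ath-miR-169m, ath-mir-169m and ath-mir-399b passed (edgeR, Benjamini-Hochberg adjusted p = 0.24, 0.252 and 0.117). Both tested members of the development and auxin list, ath-mir-396a and ath-mir-396b, were lower, also adjusted over the list alone. The structural RNA list had 17 higher and 28 lower of 154, the same adjusted over the list alone (limma's fry test, Benjamini-Hochberg adjusted p = 0.345 for a common direction and 0.00266 for changes in either). The median log2 fold change of that list was 0.24 although more of its calls were lower. The copper and oxidative stress, algal and animal lists had 0 entries, and the small RNA machinery and disease resistance lists had 0 tested members.

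In C. zofingiensis the largest rise among annotated entries was that of a U3 snoRNA, which guides the first cleavages of precursor rRNA. At chromosome 4, 421983 to 422194 of TAIR9, it went from 0, 4 and 2 reads in normal libraries to 607, 361 and 294 under stress, by 7.17 ± 0.59 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000613). The 15 tRNA entries that share the counts of chromosome 1, 25932077 to 25932149, rose by 5.32 ± 0.70, from 0, 4 and 8 reads to 295, 186 and 189 (edgeR, Benjamini-Hochberg adjusted p = 0.00105). The entry of snoR109, at chromosome 4, 11795167 to 11795267, rose by 2.95 ± 0.38, from 11, 25 and 39 reads to 373, 274 and 172 (edgeR, Benjamini-Hochberg adjusted p = 0.00105), but its commonest tag, of 12 bases and 347 reads, is with its last base removed the start of that of tRNA entries such as chromosome 5, 3324702 to 3324774. The precursor ath-mir-5660 rose by 4.06 ± 0.89, from 3, 2 and 0 reads to 56, 44 and 33 (edgeR, Benjamini-Hochberg adjusted p = 0.00782). Another tRNA entry, at chromosome 3, 5632852 to 5632924, rose by 3.39 ± 0.54 (edgeR, Benjamini-Hochberg adjusted p = 0.00157).

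Lower in C. zofingiensis was ath-mir-858b, named for a miRNA of MYB transcription factors in land plants, with 14, 20 and 21 reads in normal and 0 in each stress library, at least 8.62-fold lower, or 4.95-fold without normal replicate 1 and 17.3-fold without stress replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.00157, and 0.0716 with counts per mapping locus in limma). Its family miR858 was at -0.43 ± 0.36, with 14, 20 and 21 reads in normal and 8, 5 and 11 in stress libraries, and all of the stress reads came from another precursor (edgeR, Benjamini-Hochberg adjusted p = 0.572). The snoRNA snoU36a, at chromosome 1, 1008809 to 1008898, fell by 2.85 ± 0.42, from 48, 95 and 85 reads to 20, 10 and 14 (edgeR, Benjamini-Hochberg adjusted p = 0.00157). SNORD24 at chromosome 4, 13332873 to 13332964, fell by 2.75 ± 0.58, and snoR116 fell by 4.93 ± 0.94 (edgeR, Benjamini-Hochberg adjusted p = 0.00659 and 0.00396). U4, a spliceosomal RNA, fell by 4.06 ± 0.96, from 10, 19 and 20 reads to 4, 0 and 0 (edgeR, Benjamini-Hochberg adjusted p = 0.00983, and 0.053 without normal replicate 2). By class, 50 tRNA entries were higher and 5 lower of 181, and 3 snoRNA entries were higher and 24 lower of 48, or 14 and 4 of 67 and 3 and 15 of 33 with identical counts named once. Bacterial tRNA was not told apart from algal tRNA in these counts, and some tags listed in stress alone resembled it by eye. The most abundant tRNA entries did not pass, and the entry at chromosome 5, 3324702 to 3324774, had 56, 3060 and 762 reads in normal and 2757, 23517 and 626 in stress libraries (edgeR, Benjamini-Hochberg adjusted p = 0.31).

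Of 248 entries tested in C. zofingiensis 87 passed, 55 higher and 32 lower, or 19 and 22 when entries with identical counts were named once (edgeR's quasi-likelihood test, Benjamini-Hochberg). The replicate block turned this to 55 higher and 77 lower. With library totals alone 35 passed, 18 higher and 17 lower, and U3 and the tRNA of chromosome 1, 25932077 to 25932149, were among them, while snoR109, ath-mir-5660, the tRNA of chromosome 3, snoU36a, SNORD24, snoR116 and U4 were not. Counts per mapping locus, tested with limma in place of edgeR and chosen after seeing the data, turned the split to 24 higher and 32 lower. It was 60 and 17 with DESeq2's size factors, where the median log2 fold change was 0.05 in place of -0.30, and 193 entries passed without normal replicate 1. Of the fixed lists, the disease resistance list had 1 tested member, ath-mir-858b, which was lower, also adjusted over the list alone. The structural RNA list had 53 higher and 29 lower of 235, the same adjusted over the list alone (limma's fry test, Benjamini-Hochberg adjusted p = 0.345 for a common direction and 6.18e-06 for changes in either). Nutrient limitation, copper, development and small RNA machinery lists had 0 tested members, and the algal and animal lists had 0 entries.

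Summed by family, miRNA precursors showed 7 families higher and 1 lower of 15 tested in C. zofingiensis. The smallest adjusted p was that of miR171, a family that targets GRAS transcription factors in land plants, with 0 reads in each normal library and 36, 19 and 19 under stress, at least 4.87-fold higher, or 10.97-fold without normal replicate 1 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.51e-07). The family miR399, which acts in phosphate supply in land plants, rose by 5.18 ± 0.93, from 2, 0 and 2 reads to 46, 21 and 16 (edgeR, Benjamini-Hochberg adjusted p = 4.51e-06). A family that targets ARGONAUTE mRNA in land plants, miR168, rose by 3.75 ± 0.86, and miR408, whose land plant targets include copper proteins, by 4.20 ± 1.37 (edgeR, Benjamini-Hochberg adjusted p = 0.000213 and 0.00706, the latter 0.0626 to 0.0929 without any of the stress replicates). The families miR5660, miR859 and miR5642 rose by 5.44 ± 1.03, 2.97 ± 0.82 and 2.51 ± 1.01 (edgeR, Benjamini-Hochberg adjusted p = 9.13e-06, 0.00175 and 0.0299), and miR859 did not pass without stress replicate 1 (0.0605) or miR5642 without any single library (0.0808 to 0.235). Reads of miR850 fell by 4.18 ± 1.36, from 33, 11 and 28 to 0, 2 and 0 (edgeR, Benjamini-Hochberg adjusted p = 0.00706). With the totals of the whole annotation sheets, chosen after seeing the data, only miR850 passed, the other 7 keeping their direction (edgeR, Benjamini-Hochberg adjusted p = 0.0596 for miR171 to 0.753 for miR5642). The 2 precursors of miR168 and the 2 of miR5642 each share their commonest tag, so these sums count reads at both, and with the largest member alone 6 of 11 families passed, 5 higher and 1 lower, with neither miR168 nor miR5642 among those tested. DESeq2's size factors and library totals each gave 6 higher and 2 lower, with medians of 0.98 and 0.91 in place of 1.59.

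In C. sorokiniana 3 of 11 families passed. The family miR5645 rose by 2.66 ± 0.65, from 21, 10 and 2 reads to 106, 108 and 65, and miR5638 rose by 1.86 ± 0.62 (edgeR, Benjamini-Hochberg adjusted p = 0.0019 and 0.0154). The family miR396 fell by 1.46 ± 0.48 (edgeR, Benjamini-Hochberg adjusted p = 0.0154). Its precursors ath-mir-396a and ath-mir-396b share their commonest tag, so the sum counts reads at both, and the larger alone, chosen after seeing the data, fell by 1.34 ± 0.42 (edgeR, Benjamini-Hochberg adjusted p = 0.00977), with 76, 29 and 9 reads in normal and 21, 18 and 15 in stress libraries. The replicate block left miR5645 alone, with miR396 at adjusted p = 0.123 and miR5638 at 0.0749, and with DESeq2's size factors 5 families passed, 4 higher and 1 lower (median 0.86 in place of 0.54). Without stress replicates 1, 2 or 3 miR396 was at 0.0644, 0.0851 or 0.239, and without normal replicates 1, 2 or 3 miR5638 was at 0.236, 0.121 or 0.181. The largest family by reads, miR169, was at -0.22 ± 0.19 (edgeR, Benjamini-Hochberg adjusted p = 0.366). These names rest on Arabidopsis entries, and the commonest tags behind miR171, miR399 and miR168 in C. zofingiensis had 11, 11 and 10 bases. With the last base removed, the commonest tags of ath-mir-396a, ath-mir-396b and ath-mir-5638b in C. sorokiniana, and of ath-mir-5660 and miR168 in C. zofingiensis, lay inside more abundant tags, that of ath-mir-396a inside AAGCTGTGGGATATTA. The tag that holds that of ath-mir-5660 belongs to a group listed in stress alone. Bacterial RNA was not told apart from algal RNA in these family counts, those of miR399 included.

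**Figure D3:**
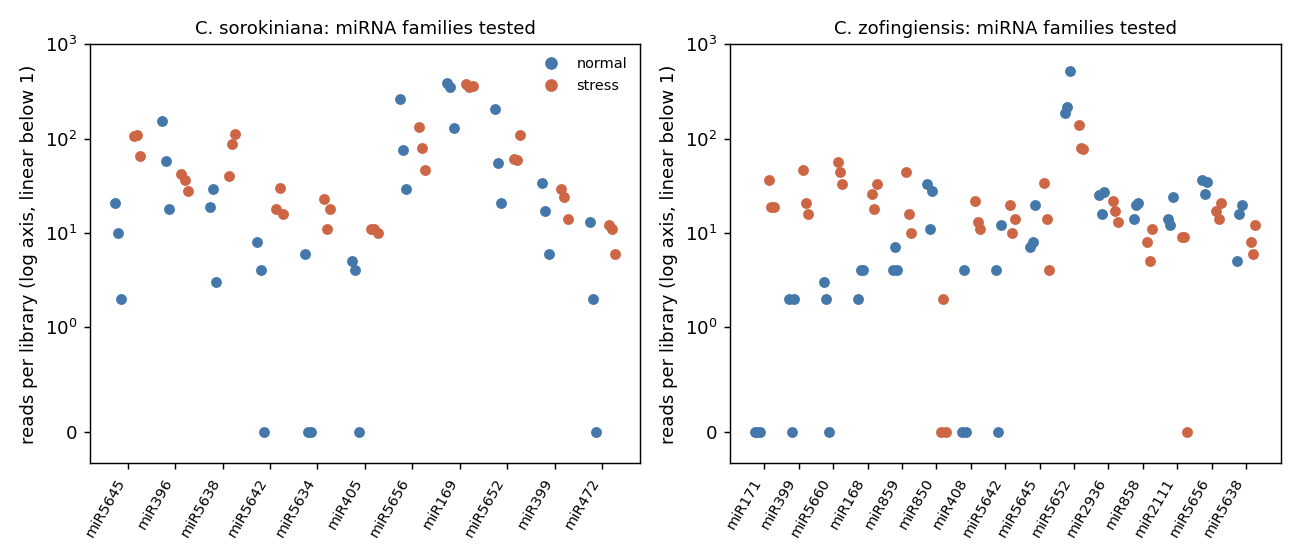
Reads per library (log axis, linear below 1, not scaled for library size) of the miRNA families tested in each species, with 1 point per library in 3 normal and 3 stress libraries. In C. zofingiensis the normal points of miR171 lie at 0 and its stress points at 19 to 36 reads, and in C. sorokiniana the stress points of miR5645 lie at 65 to 108 reads, above the normal points at 2 to 21.

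Whether the species responded differently was tested on 262 entries named in both. Different responses were called for 66 entries, 33 in each direction, or for 23 of 109 when entries with identical counts were named once (edgeR's interaction test, Benjamini-Hochberg adjusted p below 0.05). The even split did not hold with a library left out, where 15.6% to 36.4% of the calls were higher in C. zofingiensis over the 12 leave-outs. The tRNA entries of chromosome 1, 25932077 to 25932149, responded more strongly in C. zofingiensis by 6.32 ± 0.96 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 2.13e-05). The tRNA entry of chromosome 1, 26382154 to 26382225, and the precursor ath-mir-5645e responded more strongly in C. sorokiniana, by -3.16 ± 0.86 and -2.55 ± 0.83 (edgeR, Benjamini-Hochberg adjusted p = 0.00961 and 0.0272). On families, miR399 differed by 5.32 ± 1.13 and miR850 by -5.86 ± 1.51, among 3 of 15 that passed (edgeR, Benjamini-Hochberg adjusted p = 0.000107 and 0.00124), but miR399 stood for ath-mir-399b and ath-mir-399f in C. sorokiniana and for ath-mir-399d and ath-mir-399e in C. zofingiensis, with other tags. The reads of miR850 were too few to pass the filter in C. sorokiniana alone. The count depended on the processing, with 15 entries, all higher in C. zofingiensis, under DESeq2's size factors (median log2 difference -0.08 in place of -0.54), 129, 43 higher and 86 lower, with a filter of 10 counts in 3 libraries, and 38, 31 higher and 7 lower, at an adjusted p below 0.01. It was 111 without normal replicate 3 of C. sorokiniana, and 131, 101, 107 and 117 without normal replicates 1 and 2 and stress replicates 1 and 2 of C. zofingiensis.

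A deposited sheet lists 9 miRNAs predicted for C. sorokiniana at TAIR9 positions. Their mature sequences had 14 to 16 bases and their precursors 270 bases, with deposited folding energies of -65 to -46.9, and refolding gave -64.9 to -46.5. The mature sequence TGAAATTCTTGGAAG, for example, was placed on chromosome 4 between 6784701 and 6784970. None of the 9 shared 12 bases with a listed tag, a count of 0.

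In the authors' deposited table of tags, the EDGE test gave 31 tags in C. sorokiniana with an FDR below 0.05, 18 higher and 13 lower. Of these, 30 were also called here in the same direction. Baggerley's test in the same deposited table gave 69 tags with an FDR below 0.05. For C. zofingiensis the EDGE test of the authors' deposited table gave 63 tags, 32 higher and 31 lower, of which 59 were called here in the same direction. Baggerley's test gave 75 there. The tag CCTTGTATTCTTGCTTGA was 10.5-fold higher in the authors' deposited table (FDR 4.67e-13). In the annotation sheets' comparison, the authors' deposited table gave 13 entries for C. sorokiniana, all higher, of which 4 were also called here, and 0 of 337 for C. zofingiensis, with a smallest FDR of 0.117 and 46 entries at a p below 0.05. The authors' deposited table lists U3 at a normal mean of 0 and a stress mean of 31.2 (p = 0.000349, FDR 0.117). In both species the values of 0 in the authors' deposited tables matched counts per locus cut to whole numbers, in 436 of 436 and 674 of 674 comparisons.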

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

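The species difference on annotation entries was a planned test, and the same test on tags and on families was chosen after the result on entries had been seen.

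Each value here is a difference in the response to stress, C. zofingiensis minus C. sorokiniana, on the log2 scale, and each passed edgeR's interaction test with Benjamini-Hochberg adjustment. The tRNA entries of chromosome 1, 25932077 to 25932149, differed by 6.32 ± 0.96 (SE). Entries with 0 reads in every normal library of C. sorokiniana gave -8.26 for the 5S rRNA copy, -7.79 for snoR24 and -10.26 for the tRNA of chromosome 2, 9137356 to 9137427, and these fitted values depend on the prior count. Related tRNA entries on chromosome 1 that start at 17731841, 309275 and 7016516 differed by 2.82, 2.82 and 2.81, and that of chromosome 3, starting at 5632852, by 2.80. The tRNA of chromosome 1, 26382154 to 26382225, differed by -3.16, ath-mir-5645e by -2.55 and snoR114 by 5.98. Among families, miR399 differed by 5.32 ± 1.13, miR850 by -5.86 ± 1.51 and miR827 by 6.51 ± 2.00, where miR399 held other precursors in each species. In the fits of each species alone, miR827 passed the filter in neither and miR850 in C. zofingiensis only. The commonest tag of ath-mir-827 had at most 8 reads in a library of C. sorokiniana and 12 in C. zofingiensis. That of ath-mir-850 had at most 5 in C. sorokiniana. Among tags, TCGACCTGAGCTCAGGCAAGA and TCGACCTGAGCTCAGGCAAGAA differed by -12.38 and -11.77 and TGCGGAAGGATCATTGA by 9.76, values that depend on the prior count, since whole groups did not list them. GCGGAAGGATCATTGA differed by -1.11 ± 0.30, TGCCTCAGCGTCGGTA by -0.96 ± 0.28, TCGACCTGAGCTCAGGCA by -0.91 ± 0.27 and AACTCTCAACAACGGATAA by 0.76 ± 0.23 (edgeR, Benjamini-Hochberg adjusted p = 0.0437 for each).

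Of 100 splits of the 12 libraries, 2 gave as many different responses as the real 66, the real split included. The highest of the others gave 132, and it is the real labelling with the condition reversed in 1 species, so it counts the sum of the 2 stress responses. These splits exchange condition labels within a species and remove the stress responses themselves, so they did not test whether the species responded alike. For the 6 comparisons within a species, 3 libraries against 3 give 10 splits, too few for a share below 0.05. In each of these comparisons 1 split, the real one, gave as many calls, with 42 and 65 tags, 55 and 87 entries, and 3 and 8 families in C. sorokiniana and C. zofingiensis, and the highest of the other splits gave 0.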

How the results depend on the processing

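Overlap sums, tags in all 6 libraries, entries by tag length, counts per locus, whole-sheet totals and the species difference on tags and families were chosen after seeing the data. Tag calls numbered 42 in C. sorokiniana and 65 in C. zofingiensis, and moved to 20 and 21 with the replicate block, 21 and 27 for tags listed in all 6 libraries, and 11 and 22 with overlap sums. Entries, 55 and 87, moved in C. sorokiniana to 36 with DESeq2's size factors, 125 without a filter and 3 for tags of at least 16 bases. In C. zofingiensis they moved to 35 with library totals, 140 without a filter, 132 with the block (55 higher and 77 lower) and 37 with identical counts once. Counts per locus with limma in place of edgeR gave 56 there (24 higher and 32 lower). The 3 families of C. sorokiniana became 5 with DESeq2's size factors, library totals, DESeq2 or whole-sheet totals, 8 without a filter, and 1 with the block or at an adjusted p below 0.01, and the 8 of C. zofingiensis became 1 with whole-sheet totals. The 66 different responses became 15 with DESeq2's size factors, 112 without a filter, 129 with at least 10 counts in 3 libraries, 38 at an adjusted p below 0.01, 16 with identical counts once, 7 on tags and 3 on families. The block ended 15 of 26 named tag calls, 2 of 26 entry calls and 2 of 3 family calls in C. sorokiniana, and 13 of 22, 0 of 20 and 1 of 8 in C. zofingiensis. In C. zofingiensis the numbers did not meet the rule for pairing (same-numbered correlations of -0.0529 to 0.174 for tags and 0.0125 to 0.695 for entries). Leaving out 1 library gave 33 to 53 and 63 to 75 tags, 8 to 138 and 88 to 193 entries, 2 to 4 and 6 to 10 families and 53 to 131 different responses. The class share differences, in percentage points, were then -5.26 to -2.02, 0.41 to 0.698, -1.97 to -0.546 and 3.35 to 6.78 for miRNA, rRNA, snoRNA and tRNA in C. sorokiniana, and -1.56 to 0.0658, -0.12 to 0.134, -3.85 to 3.37 and -3.57 to 5.53 in C. zofingiensis. As shares of entries detected, miRNA and rRNA of C. sorokiniana differed by 0.0567 and -0.443 and rRNA of C. zofingiensis by -1.08. Directions turned for AATACCTCTGCAACATCCA (0.0142) and TTAAGTTGCTGCAGTA (0.031) with unlisted tags at the smallest listed count, for ath-miR-169m (0.111), ath-mir-169m (0.15) and the tRNA of chromosome 1, 18387802 to 18387874 (0.208) with identical counts once, and for that tRNA without normal replicate 2 (leave-outs from -1.20 to 0.0348). The cause was not tested.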

Other observations

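Tests on tags ending in A, on unlisted tags and on short tags were chosen after the patterns had been seen, while the test on moved RNA ends and the difference in A between stress and normal libraries were set before their results. A rule added after the values were seen asked that a bound be passed by more than the counting spread.

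Under stress fewer listed reads came from the commonest tags in both species, with the 10 commonest taking 58.9% ± 0.17 (SD, n = 3) in normal and 50.7% ± 5.17 in stress libraries of C. zofingiensis. Reads under 20 bases took 41.2% ± 1.95 there in normal and 49.6% ± 0.79 in stress libraries (exact permutation tests, two-sided, p = 0.1 for each, the smallest possible). In C. zofingiensis the group led by AATCTTTGAACGCATAA rose by 1.07 ± 0.25 and that of TGCTGCAGTCATACCACCACGA fell by 1.34 ± 0.41 (edgeR, Benjamini-Hochberg adjusted p = 0.00515 and 0.0198). As single tags neither lead tag passed (edgeR, Benjamini-Hochberg adjusted p = 0.092 and 0.222).

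Every tag listed in either species, 331 counted by species, ended in A. An A encoded by the RNA itself was argued against, since in 67.43% of pairs of a tag and a longer listed tag (205 of 304) the longer goes on with another base, and 62 of the 99 tags with a longer form had at least 1 such pair. A base left by adapter trimming may be the source, as at least 91.15% of the commonest tags in each library of the annotation sheets also end in A. Stress as the source of the A was argued against, since at least 91.15% of the commonest tags ended in A in each normal library too. Stress and normal means differed by at most 1.84 percentage points, but the normal means left room for a rise of only 4.53 and 3.07 points, so this difference decided nothing and a small addition under stress stays open.

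Tags unlisted in a whole group made up 67 of the 107 tag calls. Lists that stop at 100 tags stay open as the cause. When unlisted tags took the smallest listed count, 97.37% of the calls on tags listed in stress alone (37 of 38) were kept. For tags listed in normal alone 68.97% (20 of 29) were kept. The mean smallest listed share was lower in normal than in stress libraries. It was 0.106% against 0.185% in C. sorokiniana and 0.146% against 0.229% in C. zofingiensis. A tag listed in every stress library thus lay above the normal floor before any test. The share kept for such tags could therefore not speak against the lists. Ends of an RNA that moved stay open, with 17.91% (12 of 67) sharing 12 bases with a tag called in the opposite direction, 9 of 21 in C. sorokiniana and 3 of 46 in C. zofingiensis. The pooled share lies under the bound set before as speaking against moved ends. It lies there by less than its counting spread, so the added rule left moved ends open. Bacterial RNA in the stress cultures, which held glucose, may explain part of the calls, as 13.16% of the tags listed in stress alone (5 of 38, all in C. zofingiensis) hold a motif of bacterial 5S rRNA. The motif covers the end of this RNA alone, so the share is no upper limit, and other tags listed in stress alone resembled bacterial tRNA and rRNA ends by eye but had no reference to be matched to.

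Many miRNA names rest on commonest tags of 10 to 15 bases. Pieces of more abundant RNAs stay open, with 8.511% of the distinct tags (12 of 141) inside a listed, tRNA or rRNA tag against 0 of them read backwards. Conserved miRNAs stay open, with 9.929% of these tags (14 of 141) having at least 18 bases. Both shares lie under the bounds chosen as speaking against these explanations. They do so by less than their counting spread, so the added rule left both explanations open. In C. zofingiensis 51.7% of precursor counts, summed over entries, and in C. sorokiniana 24.1% came from entries whose tag lies inside another. No genome of these algae was used here, so neither can be placed.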
